A study of Homo sapiens with 6 samples.

How the data were processed

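PolyA RNA was sequenced from A549 cells, a human lung cancer line, in 3 parental libraries and 3 libraries of cells in which RAVER1 had been deleted with CRISPR/Cas9. The groups and replicate numbers were taken from the sample titles, and the series design calls the 3 libraries of a condition biological replicates. The knockout titles share the label KO2, and they do not say whether it marks 1 clone. P-values therefore measure the spread between these libraries and not the spread between independently made knockout lines.

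RNA was extracted with TRIzol and libraries were made with a stranded Illumina mRNA kit, per the labels' protocols. The authors trimmed reads with cutadapt 2.8, aligned them to hg38 with HISAT2 2.1.0, handled alignments with SAMtools 1.10 and counted them with featureCounts 2.0.0, per the submitters' processing notes. The deposited table holds 1 raw read count per gene and library, as whole numbers with no normalization. The annotation release, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Reads of overlapping or near-identical genes can therefore have been lost or assigned to the wrong gene, and values of such genes are uncertain.

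The table held 60624 genes. The 37 rows of mitochondrial genes had a count of 0 in every library, so the list of mitochondrially encoded genes could not be tested. Symbols in which hyphens had been replaced were restored for 4534 genes. Positions, exon overlaps and 3 prime UTR sequences came from GENCODE release 29 on the same genome build, joined by Ensembl gene identifier for 58437 genes. Total counts ran from 29811747 to 39910127 per library. No pair of libraries within a group agreed within sampling noise, with chi-square values per degree of freedom of 2.43 to 9.09 over genes with at least 20 counts in the pair, so all 6 libraries were kept as separate replicates.

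Fold changes were fitted with edgeR 4.0.16 in R 4.3.3. The filterByExpr function kept 16652 genes, of which 12931 were protein coding, libraries were scaled with TMM factors, and the quasi-likelihood F-test compared knockout with parental libraries with no covariate. P-values were adjusted with the Benjamini-Hochberg method over the genes kept, and an adjusted p under 0.05 counted as past the threshold. CPM values were computed in edgeR from the TMM-scaled library sizes. Standard errors were derived from the fold change and its F statistic.

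Gene lists were tested with camera in limma 3.58.1, which compares the genes of a list with all other tested genes, with a preset inter-gene correlation of 0.01. Of 31 lists, 29 had at least 5 tested members and made up 1 family for adjustment. The lists cover mesenchymal, epithelial and other cell type markers, TGFB, YAP, p53, NF-kB, interferon and other response genes, miRNA and splicing factors, and the neighbours of RAVER1. Camera with an estimated correlation and fry were run as alternatives. The fry test asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. Chromosomes were tested as sets in a family of their own.

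The tests, the lists, the rule for named genes and most of the alternatives were fixed before the data were examined. Named genes were RAVER1, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with non-overlapping groups and at least 5 CPM in the higher group, up to 4 members of each list with the smallest adjusted p among those past the threshold (up to 2 where none passed), and a fixed set of genes of epithelial-mesenchymal transition, TGFB signalling, RISC, splicing and proliferation that were named whatever their values. XIST and Y-linked genes were left out, and some genes that the rule names are not reported here. Alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, and stricter thresholds. Runs without chromosome 2, a test against a 1.5-fold change, gene families by symbol and the miRNA site test were added after the data were seen.

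The edgeR step was tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 16401 genes tested. It recovered 36 of 50 genes changed 1.25-fold, 44 of 50 changed 1.5-fold, 50 of 50 changed 2-fold and 50 of 50 changed 4-fold. It called 20 of 16171 unchanged genes tested. Apart from these genes and 30 shifted by 0.4 on the log2 scale, no gene was changed. That is a far smaller share than the 41.4% past the threshold in the real libraries. The simulation therefore did not test scaling or false calls with that many changes or with a shifted chromosome. For the miRNA site test, genes with an 8mer site in the longest annotated 3 prime UTR were compared with the other protein-coding genes outside chromosome 2, after removing trends with UTR length and GC content, and the difference was ranked among 8mers found in a similar number of genes. Over 50 permutations of the 11913 genes, a planted shift of 0.1 lay beyond 95% of matched 8mers in 47 and no shift did so in 4. Python 3.11.15 was used for this step and for the figures.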

Results

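RNA-seq read counts were analysed for 6 libraries of A549, a cell line derived from a human lung adenocarcinoma. Parental cells and cells deleted for RAVER1, an RNA-binding protein known as a cofactor of the splicing regulator PTBP1, were each represented by 3 libraries. The comparison asks how loss of RAVER1 changes gene expression, and the series title names TGFB signalling, epithelial-mesenchymal transition and the miRNA machinery as areas of interest. Total counts were 34359060, 29811747 and 32078488 in parental replicates 1, 2 and 3, and 39693041, 39910127 and 31200927 in knockout replicates 1, 2 and 3. FTL took the largest share of counts in each library, between 0.915% and 1.06%. The first principal component of log2 CPM held 78% of the variance and separated the groups.

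RAVER1 was the first gene examined because it checks the labels. RAVER1 (ENSG00000161847, hg38 chromosome 19, 10316212 to 10333640, minus strand) had counts of 2510, 1996 and 2285 in the parental libraries and 110, 112 and 79 in the knockout libraries. Its level was 69.8 ± 3.8 CPM in parental and 2.74 ± 0.17 CPM in knockout cells (SD, n = 3 each). RAVER1 fell by 4.67 on the log2 scale (SE 0.079), to 3.94% of the parental level, with an edgeR adjusted p of 1.24e-18. Exons of RAVER1 overlap those of ENSG00000267303 on the same strand and of ENSG00000274425 on the opposite strand. The counts are summed over the gene and do not show which part was deleted.

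**Figure D1:**
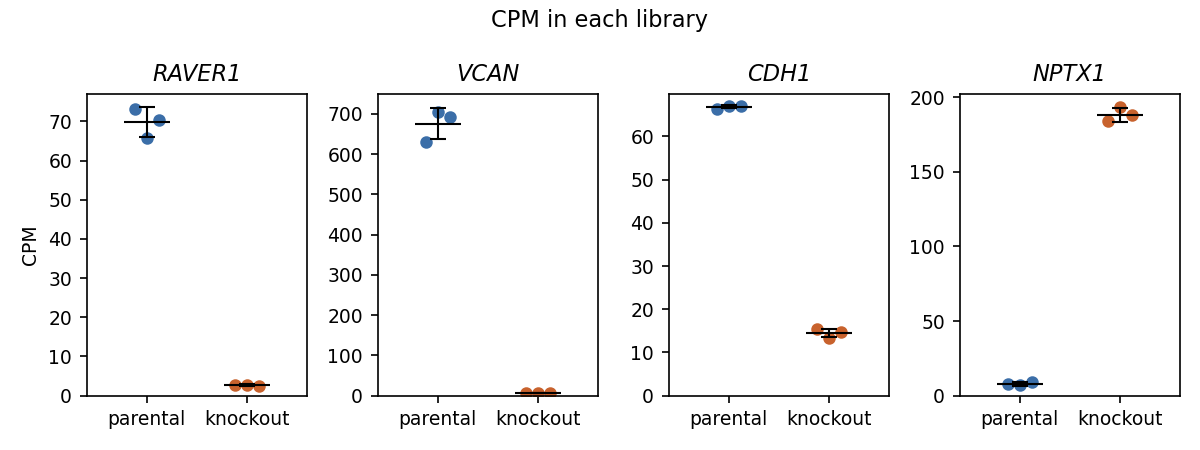
Expression in CPM (vertical axes, linear from 0) of RAVER1, VCAN, CDH1 and NPTX1 in each parental (blue) and knockout (orange) library, with bars for the mean and SD of 3 libraries. Mean RAVER1 was 69.8 CPM in parental and 2.74 CPM in knockout libraries, and the groups did not overlap for any of the genes shown.

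Transcripts that rose in knockout cells included some that were nearly absent from parental cells. ADAMTS12, a secreted metalloprotease, rose from 0.0727 to 16.5 CPM (log2 fold change 7.77, SE 0.20), and the chemokine receptor ACKR3, on chromosome 2, rose by 6.92 (SE 0.21). The carboxylesterase CES1 (6.73), TSPAN7 (5.75), CCN4 (4.82), the transporter SLCO2B1 (4.14) and LPCAT2 (3.50) also rose. NPTX1 went from 7.88 ± 1.08 to 188 ± 4.68 CPM (SD, n = 3 each), the gelatinase MMP2 rose by 4.17 and the integrin ITGB3 by 3.91. MMP2, LPCAT2 and CES1 lie close together on chromosome 16 (starts 55389700, 55508998 and 55802851), so their rises may not be independent. The window of 25 neighbouring tested genes that holds them had a median of 0.034, so the wider region did not rise. CCN4 and NDRG1, which rose by 1.37, also lie close together on chromosome 8 (starts 133191039 and 133237171). In the other direction, VCAN, which encodes the matrix proteoglycan versican, went from 676 ± 39.2 to 6.63 ± 0.677 CPM, a log2 fold change of -6.66 (SE 0.07). TM4SF4 (-6.42), C6orf223 (-6.30), SGPP2 (-5.62, on chromosome 2), the transcription factor SOX2 (-5.47), TOX3 (-5.36), UPK1B (-5.35) and HABP2 (-4.88) fell as well. FXYD2 (-5.43) and FXYD6 (-5.27) fell too, and both share exons with the readthrough gene FXYD6-FXYD2, so their reads may not be separable. All of these genes had adjusted p values of 1.23e-11 or less in the edgeR test.

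Of 16652 genes tested with edgeR, 3543 were higher and 3343 lower in knockout cells, 41.4% of the total. With upper-quartile scaling 3098 were higher and 3872 lower, so which direction held more genes depended on the scaling. Changes of at least 2-fold made up 499 of the higher and 638 of the lower genes, and the median absolute log2 fold change of the changed genes was 0.409. The groups did not overlap for 50.2% of genes, against 10% given by chance for 3 libraries against 3. Chromosome 2 held 752 of the higher and 63 of the lower genes, out of 1125 tested there, which is 21.2% of all higher genes. Without the genes of chromosome 2, an alternative added after the data were seen, 3011 genes were higher and 3005 lower.

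**Figure D2:**
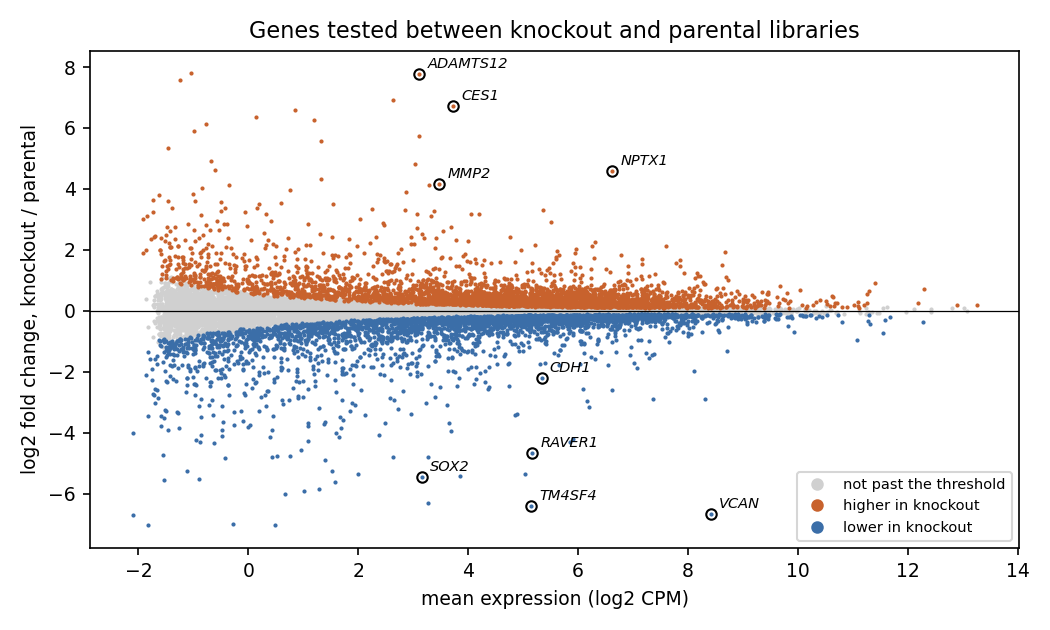
Log2 fold change of knockout over parental libraries (vertical axis) against mean expression in log2 CPM (horizontal axis) for the genes tested, coloured where past the threshold (orange higher, blue lower, grey neither), with named genes circled. VCAN lies at -6.66, RAVER1 at -4.67 and ADAMTS12 at 7.77.

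Mesenchymal markers rose and epithelial markers fell as lists. Of 27 tested mesenchymal markers, 20 were higher and 1 lower, with 21 higher and 1 lower when adjusted over the list alone, and a median log2 fold change of 0.56. MMP2 rose by 4.17, the secreted glycoprotein FSTL1 by 1.77 and the collagen COL5A2, on chromosome 2, by 1.22. The transcription factor SNAI2 rose by 2.02, while the matrix protein TNC fell (-2.49). VIM rose by 0.18 (SE 0.040) and ZEB1 by 0.29 (SE 0.093). The ZEB1 call was lost without parental replicate 1 (0.23), knockout replicate 2 (0.26) or knockout replicate 3 (0.23). CDH2, which encodes N-cadherin, stood at 0.060 (SE 0.045, edgeR adjusted p 0.312). SNAI1 (2.72), which was named after its value was seen, rose by more than SNAI2. The list had a camera adjusted p of 6.84e-12, and adjusted p = 0.0345 with an estimated correlation. Chromosome 2, whose genes had a median log2 fold change of 0.42, holds 6 of the 27 markers, and all 6 were higher.

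Of 29 tested epithelial markers, 21 were lower and 4 higher, with 22 lower and 4 higher when adjusted over the list alone, and a median log2 fold change of -0.77. CDH1, which encodes E-cadherin, went from 66.9 ± 0.372 to 14.5 ± 0.982 CPM (SD, n = 3 each), a log2 fold change of -2.20 (SE 0.06). The keratin KRT19 (-1.89) and the claudin CLDN2 (-1.59) fell, and the laminin LAMA3 rose by 1.44. For this list the camera adjusted p was 1.04e-09, and adjusted p = 0.0572 with an estimated correlation, past the threshold only with the preset. Chromosome 2 holds 2 of these markers, neither of them higher.

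Targets of TGFB signalling rose on balance. Of 39 tested TGFB response genes, 22 were higher and 8 lower, with 23 higher and 8 lower when adjusted over the list alone, and a median of 0.23. The actin-binding TAGLN rose by 1.57 (SE 0.062), ANGPTL4 by 2.05 (SE 0.088) and ADAM19 by 0.94 (SE 0.052), with 3 libraries in each group. The camera adjusted p was 2e-06, and adjusted p = 0.0667 with an estimated correlation. Of the 8 lower genes, PDGFB (-1.25), ACTA2 (-0.75), the smooth muscle actin gene, and CDKN1C (-2.09) fell most. These 3 genes were named after their values were seen. Of the 30 tested components of the TGFB and BMP pathways, 11 were higher and 7 lower, with 12 and 7 when adjusted over the list alone, and the list was not past the threshold (camera adjusted p 0.414, median 0.18). Chromosome 2 holds 6 of these components, of which 5 were higher. The ligand BMP4 fell by 3.09 and the receptor TGFBR2 by 1.02, while ID1 rose by 1.08 and ID2, on chromosome 2, by 1.32. TGFB1 rose by 0.20 (SE 0.043). TGFBR1 stood at 0.094 (SE 0.076, edgeR adjusted p 0.353), and passed the threshold without knockout replicate 1 (0.17).

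YAP and TEAD targets and integrins rose as lists. These lists are not independent of those above, since the YAP and TEAD list shares CCN1, CCN2, TGFB2 and IGFBP3 with the TGFB response genes and AXL with the mesenchymal markers, and the integrin list shares ITGAV with the TGFB response genes. Of 29 YAP and TEAD targets 19 were higher and 4 lower, with 22 and 4 when adjusted over the list alone, and a median of 0.41. CRIM1, on chromosome 2, rose by 1.23 and CCN1 by 0.83, while AMOTL1 fell by 0.70. The RhoGAP gene DLC1 rose by 5.57 from very few parental counts (5, 0 and 4), with 0.0897 CPM in parental and 4.575 CPM in knockout libraries. Of 34 integrin and focal adhesion genes 19 were higher and 8 lower, with 20 and 8 when adjusted over the list alone, and a median of 0.21. ITGB3 (3.91), ITGA11 (1.22) and CAVIN1 (0.83) rose, and ITGB4 fell by 1.97. The camera adjusted p values were 3.87e-07 and 0.000817. They became adjusted p = 0.267 with an estimated correlation for YAP and TEAD targets, and adjusted p = 0.147 with an estimated correlation for integrins.

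Markers of lung and of liver and gut lineages fell as lists, in which 11 of 26 members each had enough counts to be tested. Of 11 tested liver and gut markers 9 were lower and 2 higher, the same numbers when adjusted over the list alone, with a median of -1.73. The urea cycle enzyme CPS1 (-1.73), the cadherin CDH17 (-3.04) and the nuclear receptor HNF4G (-4.77, from 3.35 to 0.12 CPM) fell. The camera adjusted p was 4.56e-08, and adjusted p = 0.0588 with an estimated correlation. TFF1 (1.62) and CDX2 (1.44), the members that rose, were named after their values were seen. Of 11 tested alveolar and lung markers 8 were lower and 0 higher in edgeR, the same numbers when adjusted over the list alone or at an unadjusted p under 0.05, with a median of -0.24. DESeq2 and limma-voom also put 0 higher. The surfactant genes SFTPA1, SFTPA2, SFTPB, SFTPC and SFTPD and the transcription factor NKX2-1 were among the members below the low-count filter. The mucin MUC5B (-3.39), FOXJ1 (-1.69), FOXA1 (-0.83) and the lipid transporter ABCA3 (-0.36) fell. This list had a camera adjusted p of 0.0183, and adjusted p = 0.147 with an estimated correlation.

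Genes of the miRNA machinery moved both ways. Of 40 tested genes of miRNA processing and RISC, 9 were higher and 7 lower, the same numbers when adjusted over the list alone (camera adjusted p 0.86, median 0.011). AGO2, the slicing Argonaute, rose by 0.42 (SE 0.043) and TNRC6C fell by 0.39 (SE 0.081), while TNRC6A (-0.034), TNRC6B (0.0091), DICER1 (0.018) and AGO1 (0.12) were not past the threshold in edgeR. AGO1 passed it without parental replicate 2 (0.16). AGO3 rose by 0.29, a call lost without parental replicate 1 (0.23), parental replicate 3 (0.26) or knockout replicate 3 (0.21), and in DESeq2 (adjusted p 0.0539). PRKRA (0.55) and CNOT9 (0.45) rose, and both lie on chromosome 2. Of 30 tested let-7 targets 14 were higher and 0 lower in edgeR, with 15 higher and 1 lower when adjusted over the list alone or at an unadjusted p under 0.05, and a median of 0.18. DESeq2 put 0 and limma-voom 1 of them lower. MYC rose by 0.59, LIN28B by 1.81 and, on chromosome 2, RRM2 and E2F6 each by 0.49, while HMGA2 stood at -0.027 (SE 0.070). The let-7 list had a camera adjusted p of 0.0258, and adjusted p = 0.147 with an estimated correlation.

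Splicing regulators moved both ways. Of 51 tested, 9 were higher and 10 lower, the same numbers when adjusted over the list alone (camera adjusted p 0.86, median -0.0077). PTBP3 fell by 0.32 (SE 0.047) and NOVA1 by 0.90, and HNRNPA3, on chromosome 2, rose by 0.49. PTBP1 (0.048, SE 0.041), PTBP2 (-0.0077, SE 0.097) and RAVER2 (0.11, SE 0.075) were not past the threshold. Gene counts do not show exon use, so splicing itself was not analysed here.

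NF-kB, hypoxia and p53 targets rose as lists. Of 27 tested NF-kB and inflammatory genes 16 were higher and 6 lower, with 17 and 7 when adjusted over the list alone, and a median of 0.43. The growth factor CSF1 rose by 2.12, NFKB2 by 1.73 and RELB by 1.56, and the chemokine CX3CL1 fell by 4.02. The NF-kB list had a camera adjusted p of 6.1e-05, and adjusted p = 0.0588 with an estimated correlation. Of 32 hypoxia and glycolysis genes 14 were higher and 4 lower, the same numbers when adjusted over the list alone, with a median of 0.12. NDRG1 rose by 1.37, ADM by 0.88 and HK1 by 0.72. For hypoxia genes the camera adjusted p was 0.0035, and adjusted p = 0.347 with an estimated correlation. Of 31 p53 targets 15 were higher and 2 lower, the same numbers when adjusted over the list alone, with a median of 0.14. TP53I3, on chromosome 2, rose by 1.47, and CDKN1A by 0.23 (SE 0.051). For p53 targets the camera adjusted p was 0.0176, adjusted p = 0.147 with an estimated correlation, and 0.0519 without the genes of chromosome 2.

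**Figure D3:**
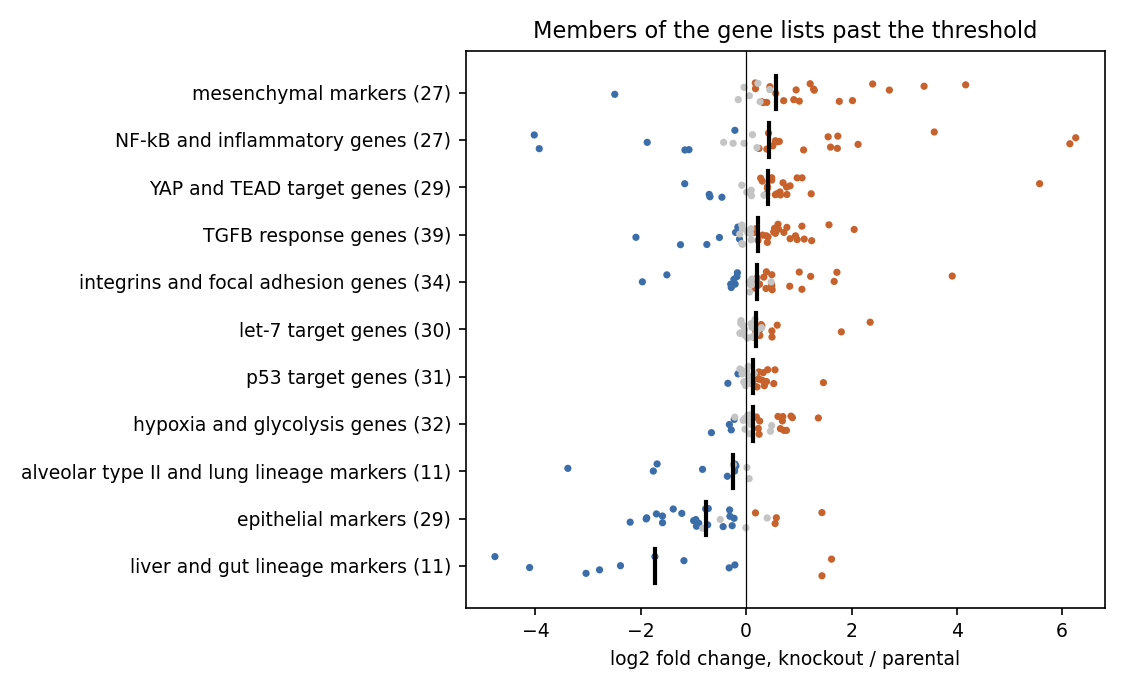
Log2 fold change of knockout over parental (horizontal axis) for each tested member of the 11 lists past the camera threshold with the preset correlation, with the number tested in brackets (orange higher, blue lower, grey neither, black bar the list median). Medians run from -1.73 for liver and gut markers to 0.56 for mesenchymal markers.

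The other lists were not past the camera threshold with the low-count filter. Without the filter, apoptosis regulators (adjusted p 0.0301), interferon-stimulated genes (0.0375), cholesterol and fatty acid synthesis genes (0.0155) and immediate early genes (0.0191) passed. Proliferation genes moved both ways, with 10 of 50 E2F and cell-cycle genes higher and 8 lower (adjusted p 0.641), and MKI67 fell by 0.20 (SE 0.043). Cholesterol and fatty acid synthesis genes had 12 of 32 lower and 6 higher (0.0854), SREBF1 fell by 0.62, and the list passed without knockout replicate 1 (0.0171). Of 35 NRF2 targets 18 were higher and 9 lower (0.308), with CYP4F11 at 3.18 and GPX2 at -2.89. Interferon-stimulated genes had 11 of 30 higher and 5 lower (0.13), with IFI16 at 3.01, and apoptosis regulators 12 of 28 higher and 5 lower (0.127), with all 5 of their members on chromosome 2 higher. Immediate early genes had 11 of 25 higher and 11 lower (0.1), with DUSP5 at 2.15 and KLF4 at -1.43. ER stress and ATF4 targets had 12 of 35 in each direction (0.86), with a median of -0.026, a mean of 0.0076 and a test direction of up. Cytosolic ribosomal proteins had 15 of 56 lower and 4 higher (0.308), and replication-dependent histones 2 of 18 lower and 3 higher (0.86). Of 25 genes near RAVER1 on 19p13.2, 9 were higher and 3 lower (0.414). Numbers adjusted over the list alone were 12 higher and 5 lower for interferon-stimulated genes, 18 and 10 for NRF2 targets, 12 and 11 for immediate early genes, 13 and 13 for ER stress genes and 4 and 14 for ribosomal proteins, and did not change for the other lists of this paragraph.

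The lists of antigen presentation genes, aryl hydrocarbon receptor targets and other cell types were not past the camera threshold either. Antigen presentation genes had 6 of 16 higher and 3 lower (camera adjusted p 0.976), with a median of 0.040 but a mean of -0.068 and a test direction of down. Aryl hydrocarbon receptor targets had 4 of 10 in each direction (0.512), with a median of 0.28, a mean of -0.037 and a test direction of up. Fibroblast and muscle markers had 3 of 6 higher and 1 lower (0.411), or 3 and 2 when adjusted over the list alone, with a median of -0.0034, a mean of -0.039 and a test direction of up. That list includes PDGFRA (1.01), which went from 0.29 CPM in parental to 0.58 CPM in knockout libraries. The PDGFRA call was lost without parental replicate 1 (0.73) or parental replicate 3 (0.97), and in DESeq2 (adjusted p 0.141). Of neuronal and melanocyte markers, 5 of 11 were higher and 1 lower (0.13), with SNAP25 at 2.62. Of 6 tested leukocyte markers 0 were past the threshold in edgeR, DESeq2 or limma-voom and 1 at an unadjusted p under 0.05 in edgeR (camera adjusted p 0.86). CD14 (-0.28), the lowest in p, passed without knockout replicate 1 (-0.40) and with upper-quartile scaling (-0.32, edgeR adjusted p 0.0431). Endothelial markers, with 4 tested members of which 2 were higher and 1 lower, were too few for camera. Among them SOX18 (0.54) lost its call without parental replicate 2 (0.40), knockout replicate 1 (0.52) or knockout replicate 3 (0.51), and in DESeq2 (adjusted p 0.147). Adjusting over the list alone did not change the other numbers of this paragraph.

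Genes of chromosome 2 were shifted upward as a set. Their median log2 fold change was 0.42 (quartiles 0.17 and 0.62), 84.7% of 1125 genes had a positive value, and the camera adjusted p was 1.83e-20, or adjusted p = 0.0334 with an estimated correlation. Chromosome 7 had a median of -0.11 (adjusted p 0.0173), and adjusted p = 0.0537 with an estimated correlation. Chromosome 11 had a median of 0.11 (adjusted p 0.0809), and passed without knockout replicate 2, when 3 chromosome sets did. The medians of the other chromosomes, Y left out, lay between -0.045 and 0.023.

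**Figure D4:**
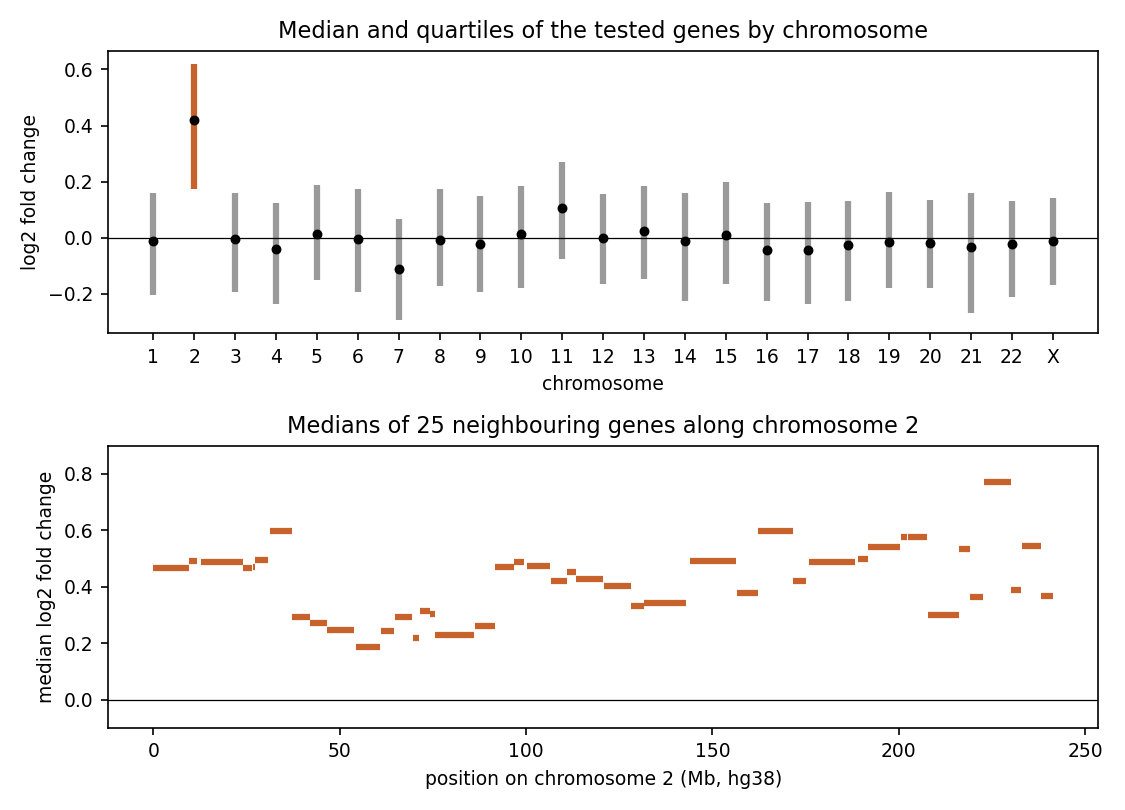
Upper panel, median (point) and quartiles (bar) of the log2 fold change of tested genes on each chromosome; lower panel, medians of 25 neighbouring tested genes along chromosome 2 against position in Mb (hg38). Chromosome 2 has a median of 0.42, and each window on it has a positive median.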

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

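The runs without chromosome 2 and the test against a 1.5-fold change were chosen after the data were seen. RAVER1 kept its direction and call in all 14 alternatives (log2 fold change -4.71 to -4.62). Leaving out 1 library gave 2934 to 3837 higher and 2864 to 3619 lower genes, 8 higher and 3 to 4 lower lists, and 2 to 3 chromosome sets. Requiring 2-fold left 499 and 638 genes, and testing against a 1.5-fold change left 575 and 664, since these criteria ask for larger changes. With an estimated correlation 1 list remained higher and 0 lower, and 1 chromosome set passed. The estimate was above the preset of 0.01 for some lists, such as YAP and TEAD targets (0.24). It was below the preset for mesenchymal markers (-0.017), let-7 targets (-0.018) and p53 targets (-0.028), among others. For those lists a higher correlation does not account for the larger adjusted p, and the cause was not tested. The fry test, which asks another question, called 17 lists higher. Without a filter 11 lists were higher and 4 lower and 1 chromosome set passed, and the cause was not tested.

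Same-numbered libraries correlated at 0.129, 0.0292 and 0.0142 in their deviations from the group means. Other pairs of a parental and a knockout library ran from -0.0931 to 0.0667, so whether the numbers pair the samples stays open. With the replicate block, 4275 genes were higher and 4071 lower, 8 lists higher and 4 lower, and 3 chromosome sets passed. The block added calls for the cholesterol list (adjusted p 0.029), AGO1 (0.0288), TGFBR1 (0.0463) and CD14 (0.0423). Not every library correlated best with its own number.

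Of 2102 values of 152 other named genes, 2068 kept direction and call. Calls were lost in 14, for PDGFRA, SOX18, ZEB1 and AGO3, and gained in 7. The 13 changes of sign were in genes not past the threshold on either side. With upper-quartile scaling TNRC6B was -0.024 and DICER1 -0.015, and without chromosome 2 PTBP2 was 0.0095. Leaving out 1 library gave -0.081 to 0.017 for TNRC6A, -0.018 to 0.042 for TNRC6B, -0.047 to 0.11 for DICER1, -0.077 to 0.060 for PTBP2 and -0.11 to 0.055 for HMGA2. Of 404 values of 29 lists, 368 kept direction and call, 16 gained a call and 11 lost one. Lists not past the threshold changed direction in 9. Adjusted p values for antigen presentation were 0.997 (upper-quartile), 0.883 (stricter filter), 0.913 (without chromosome 2), 0.866 (fry) and 0.901 to 0.967 (1 library left out). They were 0.767 to 0.92 for splicing regulators with 1 library left out, 0.866 for leukocyte markers without a filter and 0.975 for histones with the stricter filter. The cause was not tested.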

Other observations

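Tests on scaling and on COL1A2, DCN and LUM, the gene families, the site test and the runs without chromosome 2 were chosen only after results were seen. Among 39 gene families grouped by symbol, camera with the preset correlation put collagens (17 of 26 higher, 5 lower, median log2 fold change 0.53, adjusted p 0.000349) and laminins (6 of 9 higher, 3 lower, median 0.41, adjusted p 0.0108) higher in the knockout. Chromosome 2 holds 5 of the 26 collagens, and their camera adjusted p without it was 0.00915. Collagens, keratins and laminins share members with the mesenchymal and epithelial lists, such as COL5A2, KRT19 and LAMA3, so these results are not independent. Ephrins and Eph receptors (9 of 16 lower, 1 higher, adjusted p 0.0183), keratins (7 of 13 lower, 5 higher, adjusted p 0.0253) and SOX factors (5 of 11 lower, 2 higher, adjusted p 0.0108) were lower, although the median of the SOX factors was 0.021, and -0.012 with upper-quartile scaling. With an estimated correlation none of these families passed (adjusted p = 0.283 to 0.744), while RLE and upper-quartile scaling left their direction and call with the preset. COL11A1 rose by 2.20 and COL21A1 fell by 2.86, EFNB2 fell by 2.02 and SOX4 by 0.99, all named after their values were seen. All 6 tested UDP-glucuronosyltransferases were lower (median -1.32), 4 of them on chromosome 2, but the family was not past the threshold (adjusted p 0.107), and UGT1A genes share exons.

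The rise of chromosome 2 genes was weighed against technical explanations. Library scaling would shift every chromosome alike, but the largest absolute median elsewhere was 0.11 against 0.42. Removing a trend on gene length and GC content left a median of 0.418, and a rise of only a minority of the genes was argued against by the share with a positive change, 84.7% with a lower 95% Wilson bound of 82.5%, while a rise of a larger part stays open. A hypothesis is that the knockout line carries more copies of chromosome 2 than the parental line. Windows of 25 genes had a positive median in 100% of cases on both arms, from 0.19 to 0.77. With 84.7% of genes positive, raised genes scattered along the chromosome would give positive medians too, so the signs cannot tell the 2 apart. The levels held over runs of neighbouring windows. Medians were 0.466 to 0.599 up to position 37231631 and 0.187 to 0.313 from 37250502 to 91617160. The 606 windows on other chromosomes had medians from -0.524 to 0.253. Whether scattered raised genes could give such runs was not tested. On chromosome 11, windows from its start to position 86302211 also had positive medians, 0.0187 to 0.245. For comparison, 1 copy added to 3 would give 0.42 and 1 added to 2 would give 0.58. Medians of 0.19 to 0.31 over part of the short arm and up to 0.77 on the long arm leave the copy number open, and DNA was not analysed here.

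With the preset correlation, the rise of mesenchymal and fall of epithelial markers did not rest on chromosome 2. The larger of their camera adjusted p values without it was 4.31e-09. The mesenchymal median was 0.41 without chromosome 2, against 0.56 with it. No result with an estimated correlation and without chromosome 2 is reported here. Over all chromosomes the epithelial list was not past the threshold with an estimated correlation (adjusted p = 0.0572), and the gap between the list medians was 1.32 after removing the trend on length and GC content, against 1.33 before. For fibroblasts mixed into the knockout libraries, the test set in advance did not decide: 2 of 5 abundant fibroblast transcripts, COL1A1 and COL3A1, were higher, and COL1A1 was already at 48.2 CPM in the summed parental counts. By a test chosen afterwards, COL1A2, DCN and LUM summed to 0.18 CPM in the knockout, 1.11% of the gain in COL1A1, which argues against fibroblasts. A response to loss of RAVER1 and a property of the line picked after editing both remain open, since the libraries hold 1 knockout genotype.

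For the let-7 targets, a candidate explanation is weaker repression through let-7 sites. Genes with a let-7 8mer had a mean log2 fold change 0.0386 above other genes (95% interval -0.0155 to 0.0927, 522 genes), beyond 89.6% of matched 8mers. The test therefore leaves open a mean effect within this interval. A mean rise of 0.1 over these genes, a planted shift found in 47 of 50 permutations, lies above the interval. Of 20 miRNA families, 0 had an adjusted p under 0.05, with 1 at an unadjusted p under 0.05 (miR-221, 0.0268). The list stayed past the threshold without chromosome 2 (adjusted p 0.0303) with the preset, but not over all chromosomes with an estimated correlation (adjusted p = 0.147).

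The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 6886 changed genes and the highest of the others 0 in edgeR (813 at an unadjusted p under 0.05, against 7999), with 1 of 10 splits giving as many. For gene lists these were 11 and 7, with 1 of 10. For chromosome sets the real split gave 2 and another gave 7, with 8 of 10 splits giving at least as many. Every split but the real one mixes parental and knockout libraries, so the group difference adds to the spread within its groups. The 0 genes of those splits therefore say little. Camera with the preset correlation still called up to 7 lists and up to 7 chromosome sets in them. The sides of those splits hold unequal numbers of parental and knockout libraries, so part of the group difference stays in the contrast. These calls can therefore come from the real difference and do not measure false calls. Calls with the preset are still best read with the estimated-correlation values beside them.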
